A study of Arabidopsis thaliana with 8 samples.

How the data were processed

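The series holds 8 Affymetrix ATH1 arrays of Arabidopsis thaliana, accession Col-0, with 2 arrays for each of 4 genotypes: wild type (WT), a JMJ24 knockout, an IBM1 knockout and a JMJ24-IBM1 double knockout. Per the labels, RNA came from the aerial parts of seedlings aged 12 days, grown at 60% humidity under 16 h of light at 20 °C and 8 h of dark at 18 °C with 120 µmol of light per square metre and second, and amplified, biotin-labelled material was hybridised. The yield of total RNA, per the labels, ran from 16.2 to 45.5 µg. Nothing in the labels says whether the 2 arrays of a genotype came from separately grown plants, so p-values measure the spread between these samples, which may be technical. Groups and replicate numbers were taken from the labels.

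The authors' deposited values are on a log2 scale, 1 value per probe set and array, from 2.03 to 13.6, with array medians between 3.42 and 3.52. GCRMA, which corrects background by probe sequence, quantile normalises the arrays and summarises probes per probe set, is named in the submitters' processing notes, and its version is not given in the sources used here. No other filter is given there. Arrays have no read depth, and their number limits the precision.

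The table holds 22810 probe sets. The 64 control probe sets were left out of the tests and 22746 were tested. Gene names came from the platform annotation provided, updated by Entrez ID through the gene table of assembly TAIR10.1, which was used only for names and for which genes neighbour each other. In that annotation 13513 probe sets named 1 gene, 503 several and 8730 are unnamed here; 13436 of the first kind matched the gene table. A probe set with several genes or none was counted and not named by gene. With 1 probe set per gene, the one with the highest mean, 13356 genes remained. The probe sets of IBM1, JMJ24, RDR2 and DCL3 are among those unnamed here, so the planned check of the targeted genes was not run.

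A model with 1 mean per genotype was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), which leaves 4 residual degrees of freedom and added a prior worth 1.2. The contrasts were each knockout against WT, the double knockout against each single knockout, and the interaction, (double minus IBM1 knockout) minus (JMJ24 knockout minus WT). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p of single probe sets are from this limma fit unless another fit is named beside them, and those of gene lists are from camera. Arrays were also simulated with the measured means and spreads, with 200 of 22746 probe sets changed in the IBM1 knockout. For IBM1 knockout minus WT, 71% of those changed by 1 on the log2 scale were recovered, 96.5% by 2 and 96.5% by 3. These were drawn at random with independent noise, so the shares do not give the power at the measured changes. Of 310 measured rises of at least 1, 27 were called. At the others the IBM1 knockout replicates differed by 0.358 at the median, against 0.098 over all probe sets.

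The genes to be named were set by rule before the data were examined: per pairwise contrast the 10 largest rises and falls among called probe sets with an absolute log2 difference of at least 1 and no overlap between the arrays, for the interaction the 5 largest each way, where none passed the 3 lowest p in each direction, and the 4 members with the lowest p of each called list and of the silencing lists. The same plan fixed 22 gene lists of 361 genes. Only 42 of these genes were measured under a name, and each list had fewer than the 5 needed, so camera (preset correlation 0.01), its form with an estimated correlation and fry were run as planned only on the 923 annotated pseudogenes. By the fixed matching rule the alias FMO, listed for a glucosinolate enzyme, matched the gene of that symbol. Its locus is not the one listed, though it may belong to the same enzyme family. The match was kept. After the data were seen, 32 further sets were tested: symbol families of at least 8 genes, genes of the chloroplast genome, and histone demethylases by locus tag.

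Alternatives were a filter on dim probe sets (highest group mean of at least 5), quantile normalization on top, centring on array medians, limma-trend, the 2 compared groups alone, the replicate number as a block, an added fold threshold, and leaving out each array. A pseudocount was not needed for log2 values. No detection calls were used here; a group with both arrays at or below their own lower quartile, which ran from 2.49 to 2.53, was taken as near background. Its difference from a brighter group is also given as a bound, with the quartile in place of lower values, a reading chosen after seeing the data. Alternatives chosen after seeing the data were a crossed pairing of the JMJ24 and double knockout arrays and the removal of 2 arrays at once.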

Results

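The arrays compared gene expression in seedlings that lack JMJ24, IBM1 or both with that in WT. Both genes encode proteins of the jumonji family, whose members can remove methyl groups from histones; IBM1 is known to keep histone H3 lysine 9 methylation out of transcribed genes. Each of the 4 genotypes had 2 arrays. Replicate arrays correlated at 0.993 in WT, 0.992 in the JMJ24 knockout, 0.99 in the IBM1 knockout and 0.988 in the double knockout across 22746 probe sets, which are not independent replicates. Double knockout replicate 2 correlated more closely with JMJ24 knockout replicate 1, at 0.994, than with its own replicate. Likewise, double knockout replicate 1 and JMJ24 knockout replicate 2 correlated at 0.993. Such closeness was not limited to these groups: JMJ24 knockout replicate 2 and WT replicate 2 correlated at 0.994, above the replicates of either group. The probe sets of the knocked-out genes themselves could not be identified here, so the labels of the arrays have no check from known targeted transcripts.

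The first comparison asked what changes when JMJ24 alone is lost. AT2G46910, a member of the plastid fibrillin family, fell by 2.13 on the log2 scale (SE 0.0970, adjusted p = 0.0278), from 7.17 ± 0.0390 in WT to 5.03 ± 0.206 in the JMJ24 knockout (mean ± SD, n = 2). The other probe set called, whose gene is unnamed here, fell by 3.87, from 6.13 ± 0.0520 to 2.26 ± 0.0220 (n = 2, limma adjusted p = 0.0278), or by at least 3.62 against the lower quartile of the arrays, since its knockout values lay below that quartile, near background. AT4G38020, picked after its values were seen, stood at 3.81 in the knockout and 4.67 in WT, and its difference did not pass (adjusted p = 0.0989). The JMJ24 probe set is among those unnamed here, so whether the unnamed call measures JMJ24 itself cannot be told. AT3G13270, also picked after its values were seen, stood higher, at 4.32 in the knockout and 2.63 in WT, without passing (adjusted p = 0.342). No probe set rose past the threshold. The limma fit thus called 2 of 22746 probe sets, while 920 had an unadjusted p under 0.05 against 1137 expected by chance. The count was 0 without either WT array or without either double knockout array, 1 without any other array, and 0 with the replicate block.

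Loss of IBM1 was the comparison with the most calls. The largest named rise was that of AT4G16240, by 3.01 on the log2 scale (SE 0.307, adjusted p = 0.0487). AT4G16260, a gene of the beta-1,3-glucanase family of defence and cell wall enzymes, rose by 2.22, from 2.32 ± 0.0240 in WT to 4.54 ± 0.0420 (mean ± SD, n = 2, limma adjusted p = 0.00451). ATC, the homologue of the snapdragon gene CENTRORADIALIS, rose by 1.76, from 2.47 ± 0.0110 to 4.24 ± 0.0710 (n = 2, limma adjusted p = 0.00451). Among genes for proteins of the cell wall, AT3G27400, of the pectate lyase family, rose by 2.13 (adjusted p = 0.0433), and AT3G15720, a pectin lyase-like gene, rose by 1.92 (adjusted p = 0.0375). The dirigent protein genes AT3G13650 and AT1G55210 rose by 1.60 and 1.39. The lipid transfer protein gene AT3G18280 rose by 1.75, AT3G15650 by 1.96, and AT3G02480, of the late embryogenesis abundant family, by 1.70.

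The named falls were fewer. AT4G17245 fell by 1.09 (SE 0.0900, adjusted p = 0.0327) and AT5G05890, a glycosyltransferase gene, fell by 1.06 (SE 0.109, adjusted p = 0.0487). Genes outside the naming rule, picked after their values were seen, were also called. ICL, the isocitrate lyase of the glyoxylate cycle, rose by 1.09 (adjusted p = 0.0145), and BGLU15, a beta-glucosidase, by 1.05 (adjusted p = 0.0271). PDF1.2b, a plant defensin, rose by 0.75 (adjusted p = 0.0172), while PDF1.2, of the jasmonate list, was not called, at 0.56 (adjusted p = 0.682). AT3G13610, which encodes an enzyme of scopoletin synthesis, rose by 0.61 (adjusted p = 0.0167). In all, limma called 60 rises and 16 falls, and 3280 probe sets had an unadjusted p under 0.05 against 1137 expected, 1680 of them higher and 1600 lower, so the balance of the calls is not that of all probe sets. By size alone 408 probe sets differed by at least 1, 310 of them upward, of which 27 were called. The 5S ribosomal RNA control probe set also stood higher in the IBM1 knockout, at 3.68 ± 0.161, than in WT, at 2.68 ± 0.0435 (mean ± SD, n = 2).

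Of the 60 rises, 15 had WT values at or below the lower quartile on both arrays, near background, so the WT levels, SDs and adjusted p of these rest on values there and their differences are bounds. Against the quartile AT4G16260 rose by at least 2.04, AT3G15720 by at least 1.89, ATC by at least 1.73, ICL by at least 0.91 and AT3G13610 by at least 0.32.

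The calls for IBM1 loss depended on the arrays in the fit. With only the IBM1 knockout and WT arrays none were called, though the differences stayed as they were, AT4G16260 at 2.22 (adjusted p = 0.0781). None were called without either WT array or with the replicate block either, while 2 were called without either JMJ24 knockout array, 19 without either double knockout array and 165 without IBM1 knockout replicate 1. Centring arrays on their medians gave 48 rises and 23 falls, and the filter on dim probe sets 50 rises and 32 falls.

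Of the genes on lists fixed before the data were examined, 42 were measured. None was called over all genes in any contrast; adjusted over the list alone, 1 of the 42, FMO, passed for IBM1 loss and 0 in each other contrast. The 5 lowest adjusted p were in IBM1 knockout minus WT. FMO, matched by alias to a locus other than the one listed, stood 1.17 above WT (limma adjusted p = 0.0837). THI2.1, a thionin gene of the jasmonate list, stood at least 2.69 above at the group mean, its WT values lying near background (limma adjusted p = 0.138). Its IBM1 knockout arrays lay far apart, at 5.20 ± 1.29 (mean ± SD, n = 2). LHCB4.2, of the photosynthesis list, and SMZ, of the flowering list, differed by -0.20 and -0.40 (adjusted p = 0.173 and 0.176), and UF3GT, of the anthocyanin list, stood 1.23 above (adjusted p = 0.193). Of the silencing lists, DME, a DNA demethylase gene, differed by 0.10 (adjusted p = 0.478), while the histone demethylase genes AT3G45880 and LDL2 lay at or below the lower quartile on 8 and 7 of the 8 arrays, so no difference is given for them. QQS, a gene under epigenetic control, stood 1.53 above WT in the JMJ24 knockout (adjusted p = 1) and 1.27 above in the IBM1 knockout (adjusted p = 0.362). The 923 annotated pseudogenes had a median difference of 0.01 for JMJ24 loss (limma camera adjusted p = 0.0954) and -0.01 for IBM1 loss (limma camera adjusted p = 0.684). Neither shift passed, and the 4 other contrasts did not pass either, with adjusted p between 0.173 and 0.927.

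The third comparison set the double knockout against WT. AT2G46910 fell by 2.32 (SE 0.0970, adjusted p = 0.0259), to 4.85 ± 0.00500 (mean ± SD, n = 2), and the same unnamed probe set fell by 3.67, to 2.46 ± 0.0260 (n = 2, limma adjusted p = 0.0259), or by at least 3.62 against the lower quartile. These were the 2 calls, and both were also called for JMJ24 loss; lists of that length drawn independently would share 0.000176, and both comparisons use the same WT arrays, from which part of the excess may come. Across all probe sets the 2 comparisons correlated at 0.676 (covariance 0.0231), and in 100 simulations of unchanged groups at 0.498 on average (covariance 0.0148). Sharing a group of equal size gives the simulated value, with noise independent between probe sets. How much of the measured correlation comes from the shared WT arrays is thus not shown. AT4G38020 stood at 3.75 against 4.67 (adjusted p = 0.0695). AT3G13270 stood at 4.22 against 2.63 (adjusted p = 0.367). Among probe sets with an unadjusted p under 0.05 were 1260 against 1137 expected. The count was 0 without either WT or either double knockout array and 1 without any other array.

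**Figure D1:**
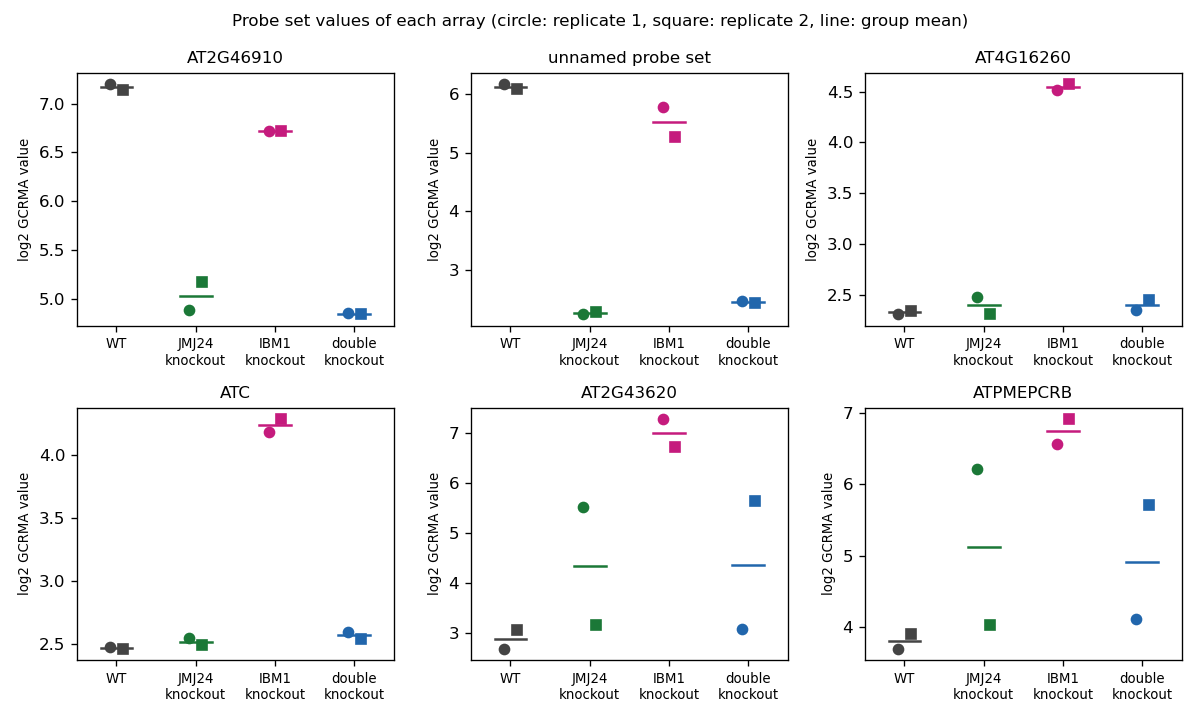
Log2 GCRMA value of 6 probe sets on each of the 8 arrays (vertical axis), by genotype (horizontal axis); circles are replicate 1, squares replicate 2 and lines group means. AT2G46910 and the unnamed probe set are low on all 4 arrays that lack JMJ24, AT4G16260 and ATC are high on both IBM1 knockout arrays, and AT2G43620 and ATPMEPCRB are high on these and on JMJ24 knockout replicate 1 and double knockout replicate 2.

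Against the IBM1 knockout, limma called 8 rises and 47 falls in the double knockout. AT4G16260 fell by 2.14 (adjusted p = 0.00538; at least 2.03 against the lower quartile), AT3G15720 fell by 1.88 (adjusted p = 0.0442), AT2G46910 fell by 1.87 (adjusted p = 0.0138), AT3G15650 fell by 1.82 (adjusted p = 0.0133) and ATC fell by 1.67 (adjusted p = 0.00538). AT3G02480 fell by 1.64 and AT3G13650 fell by 1.52. AT1G55210 fell by 1.24, AT5G10580 fell by 1.15 and AT5G39520 fell by 1.11. AT4G17245 rose by 1.03 (adjusted p = 0.0397). The unnamed probe set called for JMJ24 loss fell by 3.06 (adjusted p = 0.0146), or by at least 3.01 against the lower quartile. AT4G38020, picked after its values were seen, fell by 0.76 and was called here (adjusted p = 0.0277). AT3G13270, picked in the same way, stood 1.80 above the IBM1 knockout without passing (adjusted p = 0.061). AT4G16240, AT3G27400 and AT3G18280, named above for IBM1 loss, did not pass (adjusted p = 0.12, 0.0575 and 0.103). Of the 60 rises of the IBM1 knockout over WT, 39 were falls here. Independent lists would share 0.124, but both contrasts use the IBM1 knockout arrays, from which part of the excess may come. Across all probe sets the 2 contrasts correlated at -0.826 (covariance -0.0840), and in 100 simulations of unchanged groups at -0.5 on average (covariance -0.0149). The simulated value follows from sharing a group of equal size, with noise independent between probe sets. It does not show how much of the measured correlation comes from the shared arrays. The count was 0 without either WT or either double knockout array, 3 without either JMJ24 knockout array, 161 without IBM1 knockout replicate 1 and 0 with the replicate block.

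Against the JMJ24 knockout, the double knockout had no call with limma. The genes with the lowest p, none of which passed, were UGT73C1, a glucosyltransferase gene, with a difference of at least 0.52 against the lower quartile (adjusted p = 0.473), since its JMJ24 knockout values lay near background, AT1G63290 with 0.28 and AT5G07580 with 0.30, and on the other side AT1G21010 with -0.46 (adjusted p = 0.541), AT2G23840 with -0.41 and AT3G53980 with -0.35. Unadjusted, 762 probe sets had p under 0.05 against 1137 expected, and limma-trend called 1. At the 283 rises of at least 1 with IBM1 loss that were not called, replicates differed at the median by 0.475 in the JMJ24 knockout and 0.735 in the double knockout. That widens the spread these probe sets are tested against. It was not so at the 60 called rises, with 0.052 and 0.066, against 0.081 and 0.105 over all probe sets. Whether this accounts for the lack of calls was not tested.

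The interaction asked whether the effect of losing JMJ24 differs with and without IBM1. It was called for AT4G16260, at -2.21 (SE 0.10, adjusted p = 0.0274), ATC, at -1.71 (SE 0.0710, adjusted p = 0.0274), and AT5G10580, at -1.14 (SE 0.0610, adjusted p = 0.0444). Each stood high in the IBM1 knockout and near the WT value in the JMJ24 and double knockouts. With the replicate block the interaction had 0 calls. WT lay at or below the lower quartile for 2 of the 3 genes, and AT4G16260 did so in the JMJ24 and double knockouts too. AT5G10580 was close to that quartile, at 2.52 in WT and 2.54 in the double knockout. A difference among these groups near background, such as a fall with JMJ24 loss alone, would thus not be seen for these genes. The filter on dim probe sets leaves these genes out and gave 0 calls, quantile normalization on top also gave 0, and the count was 0 without any 1 of the WT, JMJ24 knockout or double knockout arrays, 68 without IBM1 knockout replicate 1 and 12 without IBM1 knockout replicate 2.

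Whether the double knockout carries the IBM1 response was also read array by array, on probe sets chosen from other arrays. The 100 largest rises between IBM1 knockout 1 and WT 1 stood, at the median and relative to WT 2, 2.05 higher on IBM1 knockout 2. They stood 0.61 higher on JMJ24 knockout 1 and 0.93 higher on double knockout 2, but 0.02 higher on JMJ24 knockout 2 and 0.02 higher on double knockout 1. Choosing on the other pair of arrays gave 1.74 on IBM1 knockout 1, 0.27 on JMJ24 knockout 1, 0.77 on double knockout 2, and 0.00 on both JMJ24 knockout 2 and double knockout 1. Thus within each of the JMJ24 and double knockouts 1 array stood near WT and the other partway to the IBM1 knockout. AT2G43620, a gene of the chitinase family picked after its values were seen, measured 7.28 and 6.72 in the IBM1 knockout, 5.52 and 3.14 in the JMJ24 knockout, 3.06 and 5.62 in the double knockout, and 2.68 and 3.06 in WT. ATPMEPCRB, a pectin methylesterase gene picked in the same way, measured 6.21 and 4.02 in the JMJ24 knockout and 4.11 and 5.71 in the double knockout.

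**Figure D2:**
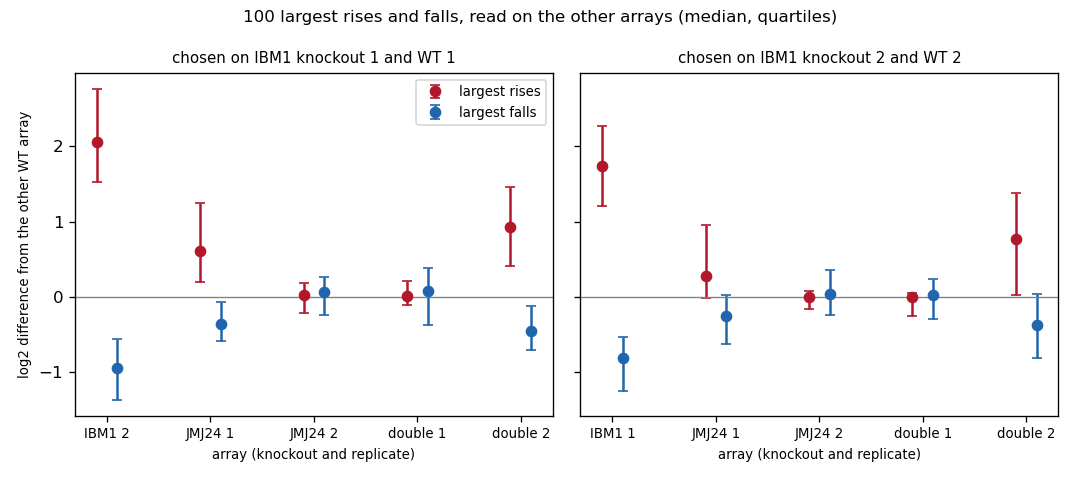
Median and quartiles of the log2 difference from the WT array left over (vertical axis), for the 100 probe sets with the largest rise (red) and fall (blue) between 1 IBM1 knockout and 1 WT array, on each array not used to choose them (horizontal axis). JMJ24 knockout replicate 1 and double knockout replicate 2 lie between the IBM1 knockout and 0, and JMJ24 knockout replicate 2 and double knockout replicate 1 lie near 0.

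Called rises were those with a low spread between replicates. Replicates of the double knockout differed by 0.07 at the median over the 60 called rises and by 0.73 over the 283 rises of at least 1 that were not called; for 10 of the 60 both double knockout arrays lay at or below the lower quartile. The called genes therefore do not stand for the whole IBM1 response in the double knockout. Across all probe sets, double minus JMJ24 knockout correlated with IBM1 knockout minus WT at 0.181 (slope 0.08), contrasts with no shared array; the value was 0.422 without double knockout replicate 1 and -0.160 without double knockout replicate 2. For JMJ24 loss the 2 backgrounds correlated at 0.008 (slope 0.01), between -0.155 and 0.195 with 1 array left out.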

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

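Tests of selected extremes, of RNA quality, of a label swap, of the shared axis and of the lowest neighbour were chosen after the result was seen. The interaction of JMJ24 and IBM1 loss passed for AT4G16260 at -2.21, ATC at -1.71 and AT5G10580 at -1.14, and had 0 calls with the replicate block. In these labels the 3 genes stood high with IBM1 loss alone and near WT with both losses. Whether JMJ24 loss alone would lower them cannot be read. Their WT values lay near background for 2 of the 3 and close to it for AT5G10580. The 5S ribosomal RNA control, outside the probe sets tested, was 1.01 higher in the IBM1 knockout than in WT and 0.04 higher in the double knockout.

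The IBM1 response was smaller in the double knockout than in the IBM1 knockout. Selection of extreme values as the whole cause is argued against for these arrays. Probe sets were chosen on 1 pair of IBM1 knockout and WT arrays. On the IBM1 knockout array left over they changed at least 2.11 times as much as on any JMJ24 or double knockout array. This holds with the labels turned too. Selection alone would on average leave that array no more changed than the others, though this sets no strict limit of 1 on the ratio. On the IBM1 knockout array left over the median changes were 2.05 and 1.74 for rises and, in size, 0.945 and 0.812 for falls. The lowest of the 4 bootstrap intervals over probe sets began at 1.45, above 1 but under the 1.5 first set for this test. Under that first bound, changed after the intervals were seen, the question would have stayed open. The intervals measure the spread over probe sets, which are not independent, and not the spread between arrays or plants. Poorer RNA in the IBM1 knockout stays open: its mean 3' minus 5' difference, 2.05, lay 0.0705 above the median of the 6 other arrays, within its replicate difference of 0.424, its RNA yields of 24 and 16.2 µg were the lowest, and the highest single array, at 2.79, was double knockout replicate 1. Plants lacking JMJ24 alone on the double knockout arrays remain open: probe sets parting the IBM1 and double knockouts from the rest were 0.444 times the highest count with other arrays in the double knockout's place, second among the 6 choices. A need for JMJ24 in the IBM1 response stays open as the biological explanation, and was not tested apart from the labels.

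Double knockout replicate 2 was closer to JMJ24 knockout replicate 1 than to its own group. With these 2 arrays beside the IBM1 knockout, 1867 probe sets parted from the other 4 arrays, against 828 with the labels as given, and 85 against 0 parted by at least 0.5. Among the 4 JMJ24 and double knockout arrays alone, 125 probe sets parted by at least 1 with these 2 as 1 group, 23 with JMJ24 knockout 1 beside double knockout 1 and 6 with the labels as given, which restates the pattern. A swap of 1 JMJ24 knockout and 1 double knockout label may account for it. The count beside the IBM1 knockout was 2.26 times that with the labels as given. That count cannot decide, since these arrays were picked for their likeness and any variation shared with the IBM1 knockout would raise it too. AT2G46910 and the unnamed probe set called with it, low on all 4 arrays that lack JMJ24, would not show such a swap. RNA quality stays open for the JMJ24 knockout arrays. Their replicates differed by 0.0440 in the mean 3' minus 5' difference against 0.424 in WT, but the controls averaged there went in opposite directions. Replicates 1 and 2 had 3.02 and 3.15 for actin, and 0.309 and 0.184 for a GAPDH control. For that GAPDH control WT had 0.309 and 0.221, a narrower difference. RNA quality stays open for the double knockout too, whose replicates differed by 0.602 in the mean. A shared axis of variation, such as growth or stress, also stays open, since the replicate differences of both groups correlated with IBM1 knockout minus WT, the lower at 0.372; the array medians and counts of the comparisons that use the JMJ24 and double knockouts depend on which of these holds, but AT2G46910, AT4G16260, ATC and AT5G10580 had similar values on all 4 of these arrays.

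The falls shared by the JMJ24 and double knockouts included AT2G46910. A change in its chromosome region stays open. The median of its 10 measured neighbours was 0.02, at percentile 72.9 of windows around other genes, which was to count against it, but such a change need not reach every neighbour: the lowest, AT2G47010, stood at -0.85, at percentile 2.65 of the lowest neighbours of such windows, though it was far from a call (adjusted p = 1 in the JMJ24 knockout and in the double knockout, each against WT). Loss of JMJ24 itself and a difference of the plant line at that gene stay open, as untested.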

How the results depend on the processing

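The alternatives that leave out 2 arrays at once, and the crossed pairing, were chosen after seeing the data. The 34 results named by the rule kept their direction under the alternatives run on them, which leave out these added ones: of 454 values, 214 kept their side of the threshold, 239 lost the call, 1 gained it and 0 turned. Direction was largely fixed beforehand, since most of these were chosen for arrays that do not overlap and several alternatives leave the difference unchanged. It is thus no test of robustness. The 34 include the genes of double minus JMJ24 knockout, which never passed and could only keep their side or gain a call. The 214 thus overstate how often a call was kept. With the replicate block 28 results lost the call, and the 6 that kept their side had never passed. The causes of the lost calls were not tested, except that fewer arrays leave fewer degrees of freedom. Whether the numbers pair the arrays is not in the labels and is left open by the values: deviations of same-numbered arrays correlate over 0.1 in 4 of the 6 pairs of groups, up to 0.208, and at 0.037 and -0.310 in the others, the last for the JMJ24 and double knockouts. The replicate block and the fit of the 2 compared groups alone gave 0 calls for every contrast they were run on, as did leaving out 2 arrays at once, JMJ24 knockout 1 with double knockout 2 or JMJ24 knockout 2 with double knockout 1. The crossed pairing gave 0 calls for double minus JMJ24 knockout. Quantile normalization on top gave 1 call for JMJ24 loss, 25 for double minus IBM1 knockout and 0 for the interaction. Limma-trend gave 5 for double knockout minus WT, 1 for double minus JMJ24 knockout and 10 for the interaction. The filter on dim probe sets gave 6 for double minus IBM1 knockout and 0 for the interaction. The fold threshold gave 29 for IBM1 loss and 22 for double minus IBM1 knockout. With 1 array left out, the lone array being assumed to vary like the others, counts ran from 0 to 1 for JMJ24 loss, 0 to 165 for IBM1 loss, 0 to 1 for double knockout minus WT, 0 to 161 for double minus IBM1 knockout, and 0 to 68 for the interaction, and stayed at 0 for double minus JMJ24 knockout. The pseudogene list was called in 0 to 1 of the lists tested in every contrast when 1 array was left out, and was called (1 list) for double minus IBM1 knockout with quantile normalization on top; these calls rest on the preset correlation of 0.01, and with the estimated one, 0.669, this contrast had adjusted p = 0.869 in the main data. The filter left 3 of its genes, so it was not run. The correlation of the IBM1 effect ran from -0.160 to 0.422 and that of the JMJ24 effect from -0.155 to 0.195 with 1 array left out. Added families called in the interaction went from 1 to 0 with an estimated correlation. Alternatives for the targeted genes IBM1 and JMJ24 were not run, as their probe sets are unnamed here. Signal near background limits the dim probe sets, 7286 having a group mean of at least 5.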

Other observations

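The tests here were chosen after the result was seen. Probe sets that part the IBM1 knockout arrays, JMJ24 knockout replicate 1 and double knockout replicate 2 from the other 4 arrays were listed by their gap. Of the 85 that parted by at least 0.5, 72 were higher on the first 4 arrays and 13 lower. This balance belongs to the wide gaps: of all 1867 that parted, 874 were higher and 993 lower. A probe set unnamed here had the widest gap, 3.16, with 7.18 and 3.11 in the JMJ24 knockout and 3.04 and 7.10 in the double knockout. CHI, JAL23, of the jacalin lectin family, and scpl35, of the serine carboxypeptidase-like family, were among the higher ones, with gaps of 0.93, 0.80 and 0.82. AT2G47880 was lower, with a gap of 0.95. These were picked by their gap. The probe set with the symbol CHI was not matched to the gene with that alias on the anthocyanin list.

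The chloroplast genome was the 1 set among the 32 added ones that passed, in the interaction: its 69 genes had a median of 0.23 (camera adjusted p = 0.0359), and adjusted p = 0.908 with an estimated correlation. The members with the lowest p were psbF, at 0.56, and psbE, at 0.49, both of photosystem II, petB, at 0.36, and rpl33, at 0.47, none of which was called. No other family passed in any contrast.

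Some genes called in the IBM1 knockout are near neighbours. Among 44 called genes 4 pairs lay within 10 measured genes of each other, AT4G16240 with AT4G16260, AT3G13610 with AT3G13650, AT3G15650 with AT3G15720 and AT5G05790 with AT5G05890, and random sets of genes had a median of 1 (permutation p = 0.0579). Neighbouring genes changing together may be a candidate explanation, but 4 pairs did not exceed the highest 5% of random sets, and AT5G05790 and AT5G05890 changed in opposite directions.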
